A study of Lens culinaris with 18 samples.

How the data were processed

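Lentil seedlings (Lens culinaris, cultivar Sultan) aged 7 days were moved to aerated nutrient solution, with or without 15% polyethylene glycol (PEG, grade 6000), a polymer that lowers the water potential of the solution and is used to impose water deficit. Per the labels' protocols, polyadenylated RNA was taken from total RNA, made into strand-marked libraries and sequenced as paired reads. The analysis used 16 libraries of root and leaf, sampled at 24 h and 96 h with and without PEG, which make 8 groups of 2 biological replicates. Of the 18 samples in the series, 2 unstressed stem samples were not analysed here.

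The deposited values are a signal per transcript, which the values themselves show to be TPM multiplied by 1 factor per library. TPM divides the reads of a transcript by its length and scales each library to 1000000. In every library 100% of the values above 0 and below 0.5 lay, within rounding, on whole multiples of the step that TPM rounded to 2 decimals would leave after scaling; chance placement would give 1.46% to 19.8% of them. FastQC 0.11.5, Trimmomatic 0.35, RSEM and edgeR are named per the submitters' processing notes, with no role or order. The deposited table is labelled as TMM-scaled. TMM is a per-library factor computed from the transcripts shared between libraries. Identifiers have the form that the Trinity assembler gives to gene-level components, so the transcripts come from an assembly without a genome. Each such component is called a transcript here. The assembler's version, the aligner and the filters are not given in the sources used here. The file does not pair identifiers with gene names, and no genome or annotation was used here.

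The depth of the libraries is unknown, because TPM keeps no read counts, so no counting intervals or detection floors are given. A value of 0 is therefore reported as listed at 0. For each tissue, limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) over its 8 libraries with 1 coefficient per group, eBayes with trend and robust options, and Benjamini-Hochberg adjustment at 0.05. Transcripts needed a value of at least 1 in at least 2 libraries of the fit. The tissues were compared in a fit of all 16 libraries, over transcripts that passed this filter in both tissues for the drought responses, and over those that passed in any for the 24 h controls. Fold changes are on the log2(value + 1) scale, which understates the changes of low transcripts. A transcript is said to have risen or fallen where its adjusted p was under 0.05. The replicates are biological, per the labels, and p-values measure the spread between these samples only.

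Overlaps of calls were tested with Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over 16 tests, beside the overlap of independent lists. Transcripts are not independent replicates, and contrasts of the same tissue share 1 estimate of spread, which can raise overlaps in any direction. Root-enriched and leaf-enriched sets held transcripts at least 4-fold apart between root and leaf in the 24 h controls at adjusted p under 0.05. They were tested at 96 h with camera at a preset correlation of 0.01 and at an estimated one, and with fry. The rule for naming transcripts, with no gene names to hand, was the 2 largest rises and the 2 largest falls over the 4 drought contrasts, each transcript once and in the contrast of its largest change, with a mean of at least 10 in the higher group and both drought libraries on the same side of both control libraries. This rule, the tests and most other settings were set before the data were examined. The planned sets were to lie at least 4-fold above both other tissues, but stem was not analysed, so root and leaf alone defined them.

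The pipeline was tested on simulated data with 100 transcripts per contrast changed by 1 log2 unit and 100 by 2. Of those changed by 2 log2 units, 53% were recovered for root at 24 h, 36% for root at 96 h, 66% for leaf at 24 h and 67% for leaf at 96 h. Of those changed by 1 log2 unit, 0% were recovered in root at either time, 11% in leaf at 24 h and 17% in leaf at 96 h. For differences between responses, recovery at 2 log2 units was 0% between the root times, 29% between the leaf times, and 41% and 48% between the tissues at 24 h and 96 h. At 1 log2 unit it was 0% between the times of either tissue, and 2% and 4% between the tissues at 24 h and 96 h. None was called in the wrong direction. The changed transcripts had a mean of at least 2 on the log2(value + 1) scale, and all other transcripts were left unchanged. Each transcript had the same spread in every group. In the data many more transcripts passed, which eases the adjusted threshold. Median absolute log2 differences between replicates ran from 0.05 in the root 96 h controls to 0.53 in the root 24 h controls. These rates are therefore not the recovery of the contrasts reported below.

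The alternatives were other pseudocounts and filters, median-ratio size factors, scaling to the same total, a replicate block, other estimates of spread, stricter thresholds, and leaving out each library. Those added after seeing the data were removal of a dominant transcript pair before scaling to the same total, a mean of at least 10, library quality weights, and removal of transcripts seen only in root at 96 h. Scaling to the same total without that removal keeps the pair in the total. It thus lowers all other transcripts where the pair takes most of a library, so its outcome in contrasts with such libraries is partly fixed in advance. Removal of the pair leaves other abundant transcripts in the total. Count tests were not run, because no whole reads could be recovered. The gene lists fixed in advance could not be matched to identifiers, and sums per gene were not needed for identifiers already at gene level.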

Results

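The expression profiles of 124151 assembled transcripts were compared in root and leaf of lentil seedlings kept with or without PEG for 24 h or 96 h, to set a short against a long water deficit. Each of the 8 groups held 2 libraries. Deposited totals, in TMM-scaled TPM, lay between 514669 and 943452 in 13 libraries. They reached 6997679 and 6699075 in the leaf 96 h drought libraries and 5832574 in root 24 h control replicate 2. Read depth was unknown.

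A pair of transcripts, TRINITY_DN47470_c0_g1 and TRINITY_DN47470_c0_g2, made up most of these 3 libraries. The pair took 81.1% and 76.3% of the total in leaf 96 h drought replicates 1 and 2, and 92.4% in root 24 h control replicate 2. It took 23.3% in root 24 h control replicate 1 and at most 0.0991% in each of the other 12 libraries. Fewer transcripts were above 0 in the 3 dominated libraries, 23194 to 24351, than in the others, where 44724 to 75080 were. Counted at a value of at least 1, the 16 libraries held 20950 to 31269 transcripts. A given value stands for a lower TPM in the 3 dominated libraries, so this count and other limits on values are not alike across libraries. The scaled step of TPM was 0.0583 to 0.0700 in these 3 and 0.00515 to 0.00943 in the others.

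**Figure D1:**
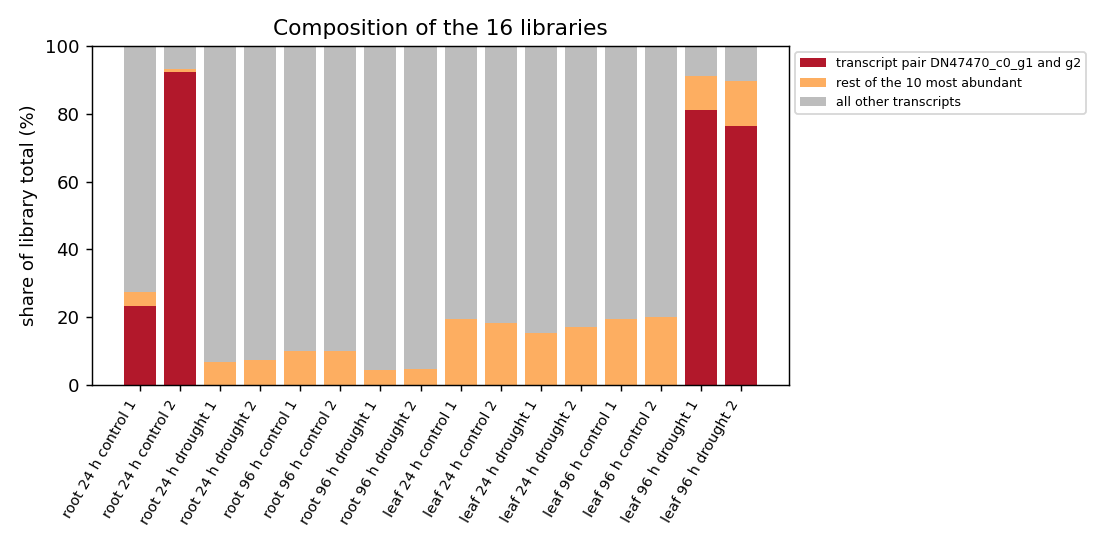
Share of each library's total (%, vertical axis) taken by the transcript pair, by the rest of the 10 most abundant transcripts and by all others, for each of the 16 libraries. The pair holds 76.3% to 92.4% of 3 libraries and 23.3% of root 24 h control replicate 1.

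Tissue was the main axis of the data. Over 26024 transcripts the first principal component held 38.2% of the variance and placed all root libraries on one side and all leaf libraries on the other. The second held 19.6%, with the leaf 96 h drought libraries at 170 and 175 and every other library at or below 45.9. The library at 45.9 was root 24 h control replicate 2, so the 3 libraries dominated by the pair lay highest. Replicate 1 of that group was at −13.2. Replicates were closest in the root 96 h controls, with a median absolute log2 difference of 0.05 over 9391 transcripts. They were farthest apart in the root 24 h controls, at 0.53, followed by leaf 96 h drought at 0.37.

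In root at 24 h of PEG, more transcripts rose than fell. Of 34082 tested, 3752 were higher and 2442 lower in drought (limma, adjusted p under 0.05), of which 2927 and 1979 changed at least 2-fold. Among abundant transcripts, with a mean of at least 100, 215 rose and 51 fell at the deposited scaling. Rises and falls there were 228 and 89 with median-ratio size factors, 179 and 86 with the pair removed and 15 and 2 with libraries scaled to the same total. The last scaling keeps the pair in the total, which by itself lowers all other transcripts in control replicate 2. From under 0.5 in both control libraries, 18 transcripts came to at least 10 in both drought libraries, and 13 went the other way. These limits, set at the deposited scaling, stand for a lower TPM in control replicate 2 than in the other libraries compared. TRINITY_DN47470_c0_g1 was at 106257 and 3720265 in the control libraries and at 37.7 and 24.1 in the drought libraries (log2 fold change −14.30, SE 1.54, limma adjusted p = 0.00471). TRINITY_DN47470_c0_g2 fell with it (−14.31, SE 1.52, limma adjusted p = 0.00454). The majority turned with the controls and the scaling: falls were 39.4% of calls, 57.2% of 10798 without root 24 h control replicate 2, 32.3% of 14570 without replicate 1, 49.5% with median-ratio size factors, 50.9% with the pair removed and 5.79% with libraries scaled to the same total. The count fell to 3039 and 1541 without drought replicate 1 or 2, to between 3128 and 3656 without any 1 of the 96 h root libraries, and to 6 when spread came from the 4 compared libraries alone.

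In root at 96 h, falls outnumbered rises. Here 8224 transcripts were lower and 4314 higher in drought (limma, adjusted p under 0.05), with 6708 and 3173 changed at least 2-fold. Below a mean of 10, 6559 of 25251 transcripts fell and 2822 rose. Between 10 and 100, 1507 of 8059 fell and 1286 rose, a majority that turned with the pair removed (1297 and 1852). At a mean of at least 100, 158 of 772 fell and 206 rose. Of transcripts at 10 or more in both control libraries, 169 were under 0.5 in both drought libraries, and 45 showed the reverse. A fall here is relative to the 96 h controls, where 9847 transcripts were higher and 2743 lower than in the 24 h controls. It need not be a loss since 24 h. The drought libraries had Spearman correlations of 0.862 and 0.866 with root 24 h control replicate 1, and 0.667 and 0.662 with replicate 2. With the 96 h controls they had 0.779 to 0.783.

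TRINITY_DN46154_c0_g1 was at 409 ± 0.161 in the root 96 h controls and 0.209 ± 0.0389 in drought (mean ± SD, n = 2 each). Its log2 fold change was −8.41 (SE 0.76, limma adjusted p = 0.000503). TRINITY_DN44605_c1_g1 was at 235 and 214 in the controls and listed at 0 in both drought libraries (limma adjusted p = 0.0118), a call lost when any 1 of the 4 libraries was left out (limma adjusted p 0.0675 to 0.0946). Without root 96 h control replicate 1 or 2 the contrast made 831 or 754 calls, 46.0% and 46.9% of them falls against 65.6% with all libraries. Without 96 h drought replicate 1 or 2 it made 7545 or 7533, with 79.5% and 79.3% falls, and without 24 h control replicate 1 or 2 it made 19334 or 19388, with 59.4% and 59.3%. Falls were 76.5% with libraries scaled to the same total.

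**Figure D2:**
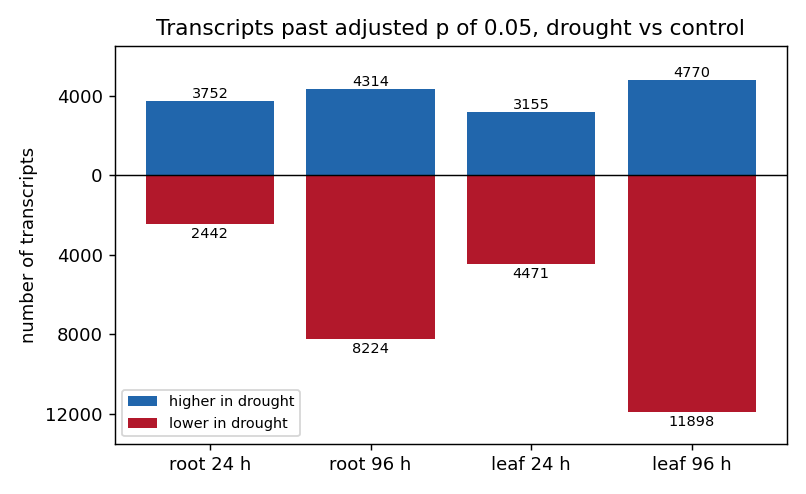
Number of transcripts (vertical axis) higher in drought, drawn upward, and lower in drought, drawn downward, at limma adjusted p under 0.05 for each tissue and time, at the deposited scaling. Falls outnumber rises in root at 96 h (8224 and 4314) and in leaf at 96 h (11898 and 4770).

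The short and long responses of root were not correlated across transcripts. Over 34082 of them, log2 fold changes at 24 h and 96 h had a Pearson r of −0.03 and a Spearman rho of −0.02. Shared rises numbered 488, against 475 for independent lists (Fisher's exact test p = 0.499, adjusted 0.499). Shared falls numbered 488, against 589 (exact p = 4.74e-07, adjusted 5.84e-07). Transcripts that rose at 24 h and fell at 96 h numbered 785, fewer than the 905 of independent lists (exact p = 8.79e-07, adjusted 1.00e-06), but were in excess without root 96 h control replicate 1 (59 against 27.0) or 2 (52 against 25.1) and root 24 h drought replicate 1 (507 against 423) or 2 (375 against 230). Those that fell at 24 h and rose at 96 h numbered 683, against 309 (exact p = 5.14e-99, adjusted 1.37e-98). This last excess was present with median-ratio size factors (1026 against 483), with the pair removed (1158 against 477) and with each root library left out (105 against 15.1 without root 96 h control replicate 2, 2404 against 1466 without root 24 h control replicate 2). Shared falls lay above independent lists without root 96 h control replicate 1 (47 against 14.3) or 2 (43 against 13.3) and without root 24 h drought replicate 1 (357 against 294) or 2 (136 against 133). Shared rises lay below them without root 24 h control replicate 2 (969 against 1096) and either 96 h control replicate (24 against 31.7 and 22 against 28.4). They lay above them without root 24 h control replicate 1 (2560 against 2354), root 24 h drought replicate 1 (388 against 208) or 2 (161 against 113), and root 96 h drought replicate 1 (160 against 111) or 2 (135 against 111). With the pair removed they numbered 521 against 460 (exact p = 0.00199).

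Tested directly, the root response differed between the times for 13011 transcripts (limma interaction, adjusted p under 0.05). It was lower at 96 h for 8850 of them and higher for 4161. TRINITY_DN46154_c0_g1 was among the former: at 24 h it stood at 1.07 and 0 in control and at 24.5 and 4.25 in drought (limma adjusted p = 0.0467, 0.0652 with the pair removed and 0.135 with libraries scaled to the same total). The number of interactions was 2039 or 1987 without root 96 h control replicate 1 or 2, and 20419 without root 24 h control replicate 1. The share lower at 96 h was 68.0%, and 83.7% with libraries scaled to the same total.

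In leaf at 24 h, 4471 transcripts fell and 3155 rose of 28176 tested (limma, adjusted p under 0.05), with 3184 and 1829 changed at least 2-fold. Abundant transcripts, with a mean of at least 100, moved both ways, 307 up and 299 down as deposited, 274 and 319 with median-ratio size factors, and 362 and 252 with the pair removed. From under 0.5 in both controls, 65 transcripts came to at least 10 in both drought libraries, and 49 went the other way. TRINITY_DN46154_c0_g1 fell from 36.2 ± 7.82 to 3.67 ± 0.126 (mean ± SD, n = 2 each). Its log2 fold change was −2.98 (SE 0.16, limma adjusted p = 0.000275). Falls were 58.6% of calls at the deposited scaling, 63.7% with median-ratio size factors, and a minority of 46.9% with the pair removed and 45.5% with libraries scaled to the same total. The count was 2894 or 2895 without leaf 24 h control replicate 1 or 2, 4533 without drought replicate 2, and 12500 or 12511 without leaf 96 h drought replicate 1 or 2.

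In leaf at 96 h, 11898 transcripts fell and 4770 rose (limma, adjusted p under 0.05), with 9744 and 3723 changed at least 2-fold. Among abundant transcripts, with a mean of at least 100, 493 fell and 280 rose at the deposited scaling. The majority there turned with the scaling, with falls at 63.8% of calls as deposited, 48.8% with median-ratio size factors, 79.7% with the pair removed and 92.2% with libraries scaled to the same total. From under 0.5 in both controls, 240 transcripts came to at least 10 in both drought libraries, and 229 went the other way. These limits, set at the deposited scaling, stand for a lower TPM in the drought libraries than in the controls. Both drought libraries of this contrast were dominated by the pair.

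TRINITY_DN47470_c0_g1 rose from 120 ± 18.0 to 3905948 ± 288719 and TRINITY_DN47470_c0_g2 from 48.7 ± 9.65 to 1486935 ± 111936 (mean ± SD, n = 2 each). Their log2 fold changes were 14.99 (SE 0.14, limma adjusted p = 1.45e-06) and 14.88 (SE 0.16, limma adjusted p = 1.53e-06). TRINITY_DN46154_c0_g1 rose from 81.8 ± 0.293 to 440 ± 47.1 (mean ± SD, n = 2 each) at the deposited scaling, a log2 fold change of 2.41 (SE 0.16, limma adjusted p = 0.000122). The change was 2.96 with median-ratio size factors and 1.54 with the pair removed, but a fall of −0.68 with libraries scaled to the same total (limma adjusted p = 0.0172). TRINITY_DN44605_c1_g1 was at 49.6 and 37.0 in the controls and listed at 0 in both drought libraries (limma adjusted p = 3.41e-05). The median log2 fold change of all tested transcripts was −0.59 at the deposited scaling, −0.24 with median-ratio size factors, −1.07 with the pair removed and −1.99 with libraries scaled to the same total. Falls were 71.4%, 58.1%, 85.5% and 97.1% of calls in the same order. The last scaling keeps the pair in the total, which by itself lowers all other transcripts in both drought libraries. Its values therefore say little about the response of those transcripts.

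The leaf responses at the 2 times overlapped. Across transcripts, the log2 fold changes had a Pearson r of 0.37 and a Spearman rho of 0.33. Shared rises numbered 1299, against 534 for independent lists (Fisher's exact test p = 1.69e-263, adjusted 1.36e-262), and shared falls 2977, against 1888 (exact p = 7.22e-281, adjusted 1.15e-279). Only 254 transcripts fell at 24 h and rose at 96 h, against 757 for independent lists, and 806 rose and then fell, against 1332. Calls shared in direction numbered 4276 and ranged from 1914 without leaf 24 h control replicate 2 to 6666 without leaf 96 h drought replicate 2, above independent lists each time in both directions. The response differed between the times for 12721 transcripts (limma interaction, adjusted p under 0.05), being lower at 96 h for 8605. This split followed the scaling: 67.6% were lower at 96 h as deposited, 49.2% with median-ratio size factors, 86.2% with the pair removed and 95.0% with libraries scaled to the same total. The count was 8043 or 8088 without leaf 24 h control replicate 1 or 2, and 7816 or 7773 without leaf 96 h control replicate 1 or 2.

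**Figure D3:**
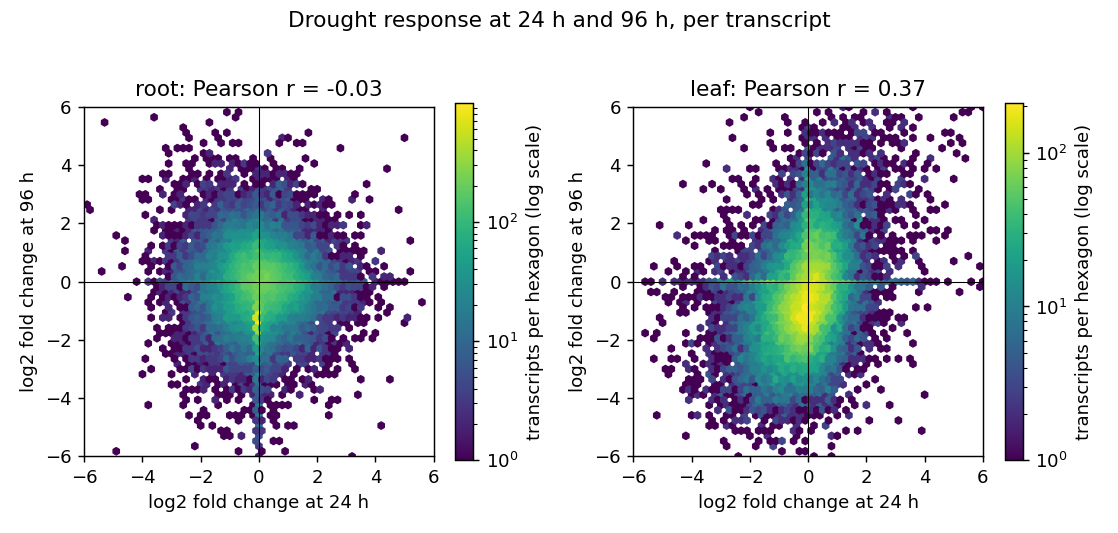
Log2 fold change (drought against control) at 24 h on the horizontal axis and at 96 h on the vertical axis, for root and leaf. Colour gives the number of transcripts per hexagon on a log scale, within 6 log2 units of 0. Pearson r across transcripts was −0.03 in root and 0.37 in leaf.

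Root and leaf shared more of their response at 24 h than at 96 h by correlation, although the difference between these correlations was not tested. At 24 h the tissues shared 819 rises, against 336 for independent lists (Fisher's exact test p = 2.04e-157, adjusted 1.09e-156), and 651 falls, against 274 (exact p = 2.82e-117, adjusted 9.04e-117), with a Pearson r of 0.31 across 22510 transcripts. At 96 h they shared 591 rises, against 455 (exact p = 5.57e-13, adjusted 7.42e-13), and 1936 falls, against 1604 (exact p = 2.76e-34, adjusted 4.42e-34), with a Pearson r of 0.11. With single libraries left out, calls shared in direction ranged from 510 without root 24 h drought replicate 2 to 2368 without root 24 h control replicate 1 at 24 h, and from 230 without root 96 h control replicate 2 to 4340 without root 24 h control replicate 2 at 96 h, above independent lists each time. The overlap at 24 h depended on the spread used for root. With spread from the 4 compared libraries alone, calls shared in direction went from 1470 to 1 at 24 h and from 2527 to 3962 at 96 h. With libraries scaled to the same total they were 169 at 24 h, of which 168 were rises, and 792 at 96 h. Responses differed between the tissues for 3802 transcripts at 24 h and 10749 at 96 h (limma interaction, adjusted p under 0.05). At 24 h 32.6% of the differing transcripts were lower in root than in leaf, a share of 65.8% with the pair removed and 16.3% with libraries scaled to the same total. The 24 h count was 8190 without root 24 h control replicate 1, and 1992 to 2500 without either leaf 24 h control, either leaf 24 h drought library or root 24 h drought replicate 2. At 96 h the share was 26.9%, and 43.3%, 11.6% and 3.11% with median-ratio size factors, the pair removed and libraries scaled to the same total.

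Transcripts typical of a tissue were followed as groups. In the 24 h controls, 5299 transcripts were higher in root and 7648 higher in leaf (limma, adjusted p under 0.05). The majority turned with the pair removed, when 31.4% were higher in leaf against 59.1% as deposited and 83.7% with libraries scaled to the same total. It turned also without root 24 h control replicate 2, with 7598 higher in root and 6432 in leaf. At a 4-fold minimum, 1765 transcripts were root-enriched and 2897 leaf-enriched. This membership, set at the deposited scaling with all libraries, was kept under every other scaling and with each library left out. The ranges below therefore do not cover changes in membership.

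Root-enriched transcripts rose as a group in root at 96 h relative to other transcripts. Of the 1765, 458 rose and 233 fell, and their median log2 fold change was 0.28 against −0.14 in the rest (camera adjusted p = 5.97e-05, 0.136 with an estimated correlation). The difference of 0.43 ranged from 0.19 to 0.55 with single root libraries left out, and was lowest without root 96 h control replicate 1. With libraries scaled to the same total 76 rose and 73 fell. Leaf-enriched transcripts were lower than others in leaf at 96 h. Of the 2897, 428 rose and 1697 fell, with a median of −1.17 against −0.54 (camera adjusted p = 0.00292, 0.362 with an estimated correlation). That set's median was −0.75 with median-ratio size factors, −1.84 with the pair removed and −3.20 with libraries scaled to the same total. In leaf at 96 h, the 880 tested root-enriched transcripts divided into 248 rises and 245 falls, with a median of 0.01 against −0.60 (camera adjusted p = 0.00067, 0.249 with an estimated correlation). The even division held only as deposited: rises and falls were 303 and 202 with median-ratio size factors, 166 and 356 with the pair removed and 55 and 574 with libraries scaled to the same total. The set's own median was 0.33, −0.46 and −1.30 in the same order. Leaf-enriched transcripts in root at 96 h, with 189 rises and 489 falls among 2118, did not stand apart (median −0.28 against −0.11, camera adjusted p = 0.376, 0.853 with an estimated correlation). Without root 96 h control replicate 1 or 2 that set did pass (camera adjusted p = 0.00312 and 0.00292).

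At 24 h the sets and the contrasts share control libraries, which lowers a tissue's own set in drought with no effect at all, so these values are description only. Root-enriched transcripts in root at 24 h had a median of −1.26, with 121 rises and 547 falls. With libraries scaled to the same total their median was 0.11, with 36 rises and 53 falls. Leaf-enriched transcripts in leaf at 24 h had a median of −0.97, with 226 rises and 1536 falls.

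**Figure D4:**
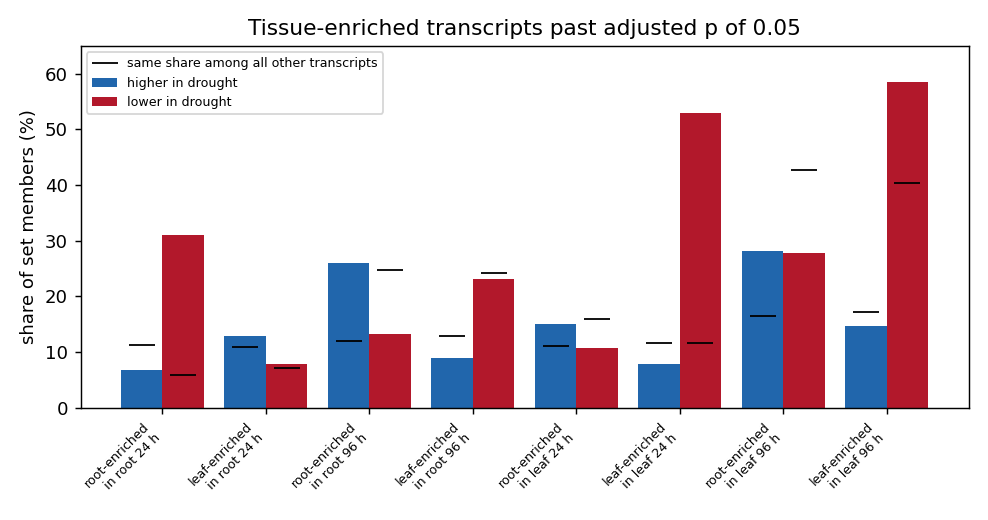
Share of set members (%, vertical axis) past limma adjusted p of 0.05 in each direction, for root-enriched and leaf-enriched transcripts in the 4 drought contrasts. Black marks give the same share among all other transcripts. In root at 96 h, 25.9% of root-enriched transcripts rose, against 11.9% of the others, and in leaf at 96 h 58.6% of leaf-enriched transcripts fell, against 40.4%.

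Unstressed seedlings also changed between the days. In root, 9847 transcripts were higher and 2743 lower in the 96 h than in the 24 h controls (limma, adjusted p under 0.05). Of the root calls 21.8% were lower at 96 h as deposited, 31.4% with median-ratio size factors, 24.1% with the pair removed and 2.48% with libraries scaled to the same total. In leaf, 3610 were higher and 3911 lower. TRINITY_DN46154_c0_g1 was higher at 96 h in the controls of both tissues, by 8.15 log2 units in root (SE 0.76, limma adjusted p = 0.000518) and 1.17 in leaf (SE 0.16, limma adjusted p = 0.00407). Root counts were 1693 or 1656 without root 96 h control replicate 1 or 2, and 20584 without root 24 h control replicate 1. In leaf, 52.0% of calls were lower at 96 h as deposited, and 41.4% and 40.1% with the pair removed and with libraries scaled to the same total. It was 54.8% with median-ratio size factors. The share was 43.2% and 44.0% without leaf 24 h control replicate 1 or 2, and 61.5% and 60.4% without leaf 96 h control replicate 1 or 2, while single left-out libraries gave 2924 to 12207 calls.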

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

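The 3 tests on the transcript pair, the test of summed library shares in root at 96 h, and the reading of abundant transcripts under 3 scalings were chosen only after the results were seen.

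Each response of a named transcript below differed between times or tissues by limma's interaction test, at adjusted p of 0.00312 or less. The fitted drought response of TRINITY_DN47470_c0_g1 was higher at 96 h than at 24 h, by 15.76 log2 units in root (SE 2.18, limma adjusted p = 0.00312) and 15.44 in leaf (SE 0.20, limma adjusted p = 1.37e-05). In root the transcript fell at 24 h (−14.30) and was not called at 96 h (1.46, SE 1.54, limma adjusted p = 0.519). The root difference rests on the 24 h controls, at 106257 and 3720265, against 24.1 to 365 in the other root libraries. In leaf the transcript rose at 96 h (14.99). Its root response minus its leaf response was −13.85 at 24 h and −13.53 at 96 h. TRINITY_DN47470_c0_g2 gave 15.99 in root and 15.30 in leaf between the times, and −13.89 at 24 h and −13.20 at 96 h between the tissues. TRINITY_DN46154_c0_g1 gave −11.41 in root and 5.38 in leaf between the times, the latter 2.16 with libraries scaled to the same total, and 5.98 at 24 h and −10.82 at 96 h between the tissues. For TRINITY_DN44605_c1_g1 in leaf the fitted value between the times was −5.45, which depends on the pseudocount because the transcript is listed at 0 in 6 of the 8 leaf libraries. Over all transcripts, 13011 responses differed between the times in root, 12721 in leaf, 3802 between the tissues at 24 h and 10749 between the tissues at 96 h.

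The first pattern is the transcript pair that held most of 3 libraries. A response to water deficit common to both tissues and times is argued against. In root at 24 h each control library lay above each drought library by at least 11.46 log2 units. The pair took over 1% of a drought library only in leaf at 96 h. The bound was written after the values were seen, and it does not bear on a response of leaf at 96 h alone. There the pair took 81.1% and 76.3% of the drought libraries and at most 0.0236% of the controls, so such a response stays open. A leaf sample in place of root 24 h control replicate 2 is also argued against, because its highest Spearman correlation with a root library exceeded its highest with a leaf library by 0.248. The ratio of the 2 members differed by 1.24 times at most between the 4 libraries where the pair took over 1%, but it lay between 1.94 and 2.68 in all 16 libraries, so it singled out no source, and its bound was set aside after its value was seen. Whether 1 RNA source holds both members, and whether reads were shared between near-identical sequences, stays open, and no other biological explanation was tested.

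The second pattern is the majority of falls in leaf at 96 h. Water deficit as at 24 h stays open: the leaf responses at the 2 times had a Pearson r of 0.373, but a shift of all fold changes leaves r as it is, falls at 24 h were 63.7% of calls with median-ratio size factors and 46.9% with the pair removed, and the bound on r was set aside after its value was seen. The authors' scaling of libraries ruled by the pair cannot be told apart from it, since falls were 58.1% of calls with median-ratio size factors and 85.5% with the pair removed. Removing the pair did not free the total of dominant transcripts. The pair took 81.1% and 76.3% of the leaf 96 h drought libraries, and the 10 most abundant transcripts 91.0% and 89.6%. In the other leaf libraries the 10 most abundant took 15.3% to 20.0%. The 85.5% may therefore be raised by the scaling itself. A shallow remainder left by the pair is also open: among transcripts with a mean of at least 100 falls were 63.8% of calls, and at least 63.7% with any 1 leaf library left out, which met the bound set in advance against this explanation. That bound was written for the deposited scaling alone, and the same share was 48.8% with median-ratio size factors and 79.7% with the pair removed, so it was set aside after its value was seen.

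The third pattern is the majority of falls in root at 96 h. There a group of 4176 transcripts was under 0.5 in all 12 other libraries and at 1 or more in at least 2 of the 4 root 96 h libraries. The choice thus used the libraries that the contrast compares. These transcripts gave 3409 falls and 373 rises. They took 1.45% and 1.49% of the control libraries against 0.326% and 0.301% of the drought libraries. Without them falls were 55.7% of calls, between the bounds set in advance, so RNA from a source present only in these libraries cannot be told apart from a response of the root. Without 96 h root control replicate 1 or 2 falls were 46.0% and 46.9% of calls with the group and 48.3% and 49.3% without it, and without drought replicate 1 or 2 they were 79.5% and 79.3% with it and 63.6% and 63.3% without it. Greater depth of the controls stays open over all transcripts, since the number at 1 or more was 1.199 to 1.241 times that of the drought libraries. It stays open for the 4176 too: their summed share in the controls was 4.46 to 4.95 times that in drought, but 0.316 to 0.355 times for 504 chosen on the drought libraries and 1.96 to 2.22 times for 44425 above 0 in any, so that bound was set aside after its value was seen.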

How the results depend on the processing

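Alternatives that weighted libraries, removed the transcript pair, required a mean of at least 10 or removed transcripts seen only in root at 96 h were chosen after seeing the data. The cause was not tested for any change below, except where fewer transcripts or libraries entered the fit. The pair's rises in leaf at 96 h kept their direction in every alternative that refitted the pair, which was absent after its removal. So did the falls of the other 2 named transcripts in root at 96 h. All passed adjusted p under 0.05 there, except TRINITY_DN44605_c1_g1 with single libraries left out. TRINITY_DN44605_c1_g1 (limma adjusted p = 0.0118) also did not reach the stricter threshold of adjusted p under 0.001. Other pseudocounts, median-ratio size factors, removal of the pair and eBayes without trend moved no total of calls, both directions together, by over 1.5 times. Single directions moved more. With the pair removed, transcripts higher in root in the 24 h controls went from 5299 to 10634 and rises in leaf at 96 h from 4770 to 2829. With median-ratio size factors, rises shared by root and leaf at 96 h went from 591 to 936. Unknown depth limits all calls near a value of 1.

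With no filter, calls were 25420 for root at 96 h, 20130 for the root interaction between times, 23668 for root controls between times and 16146 for the tissue interaction at 96 h. Calls shared in direction were then 520 between root times, 2773 between leaf times and 679 between tissues at 24 h. A minimum of 5 gave 6102, 6299 and 5916 calls for the first 3 of these. With libraries scaled to the same total, calls were 1728 for root at 24 h, 12099 for leaf at 24 h, 22690 for the leaf interaction, 11485 for leaf controls, 836 for the tissue interaction at 24 h and 6232 for the tissues in controls. Shared calls were 68 between root times, 169 between tissues at 24 h and 792 between tissues at 96 h. A mean of at least 10 gave 3557, 3213, 4168 and 6717 calls for root at 24 h and 96 h and leaf at 24 h and 96 h. It gave 3434 and 5325 for the root and leaf interactions, 3109 and 3751 for root and leaf controls, 1888 and 3721 for the tissue interactions at 24 h and 96 h, and 5490 for the tissues in controls. Shared calls were then 650 between root times, 2602 between leaf times and 1081 between tissues at 96 h.

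Library weights gave 1419 calls for root at 24 h, 22263 for root at 96 h, 11642 for leaf at 24 h, 7835 for root controls, 14422 for leaf controls and 1972 for the tissue interaction at 24 h. Shared calls were 366 between root times, 610 between tissues at 24 h and 4109 at 96 h. Spread from the 4 compared libraries gave 6 calls for root at 24 h and 21556 at 96 h, with 1 shared between root times, 1 between tissues at 24 h and 3962 at 96 h. Spread from all 16 libraries gave 1502 shared between root times. At a 2-fold minimum, leaf at 24 h had 5013 calls, and 525, 2512, 771 and 1542 were shared between root times, leaf times, tissues at 24 h and tissues at 96 h. At adjusted p under 0.001 and 4-fold, 31, 1049, 700 and 4012 calls were left for root at 24 h and 96 h and leaf at 24 h and 96 h. Without transcripts seen only in root at 96 h, calls were 7803 for root at 96 h, 8377 for the root interaction and 8057 for root controls.

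For the sets, the median difference from other transcripts was 0.43 for root-enriched in root, 0.61 for root-enriched in leaf and −0.63 for leaf-enriched in leaf. These lost their camera call with an estimated correlation (adjusted p 0.136, 0.249 and 0.362). Fry tests a set against no change and not against other transcripts, and by it the root-enriched set in leaf, with a median of 0.01, did not pass (adjusted p = 0.977). Leaf-enriched in root passed with a minimum of 5 (−0.39), a mean of at least 10 (−0.34) and 16-fold sets (−0.40). Its camera direction reversed with libraries scaled to the same total (−0.077, adjusted p = 0.273) and with the pair removed (−0.085, adjusted p = 0.786).

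With 1 library left out, the lone library of its group was assumed to vary like the other groups. Calls then ranged from 1541 to 14570 for root at 24 h, 754 to 19388 for root at 96 h, 2894 to 12511 for leaf at 24 h and 11915 to 18415 for leaf at 96 h. The root interaction ranged from 1987 to 20419, the leaf interaction from 7773 to 16173, root controls from 1656 to 20584 and leaf controls from 2924 to 12207. Tissue interactions ranged from 1992 to 8190 at 24 h and 8233 to 13021 at 96 h, and tissues in controls from 9138 to 16394. Shared calls ranged from 65 to 3914 between root times, 1914 to 6666 between leaf times, 510 to 2368 between tissues at 24 h and 230 to 4340 at 96 h. Set differences ranged from 0.19 to 0.55 for root-enriched in root, −0.30 to −0.12 for leaf-enriched in root, 0.53 to 0.69 for root-enriched in leaf and −0.73 to −0.49 for leaf-enriched in leaf.

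Replicates share numbers across groups, but same-numbered libraries did not deviate together (correlations of 0.034 and 0.00496 for root at 24 h and 96 h, −0.0738 and −0.0475 for leaf), so the numbers were not taken as pairs. A replicate block gave 4634, 11572, 6506 and 16149 calls for root at 24 h and 96 h and leaf at 24 h and 96 h. It moved the calls shared between root times from 976 to 641 and no other total of both directions by over 1.5 times. Falls shared by root and leaf at 24 h went from 651 to 422. Not run were the stem contrasts, sums per gene, the gene lists and count tests.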

Other observations

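The sets of 50 transcripts below were chosen after the data were seen, on the 24 h controls. The 50 most abundant leaf-enriched transcripts were mostly lower in drought in both tissues at 96 h. In leaf at 96 h, 41 of the 50 fell and 8 rose (limma, adjusted p under 0.05), with a median log2 fold change of −2.36, and 41 fell with median-ratio size factors and with the pair removed. In root at 96 h, 37 of the 49 tested fell and 3 rose, with 36 and 30 falls under the same scalings. In leaf at 24 h, where the contrast shares the control libraries that chose the set, 41 fell and 1 rose.

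Their summed share of the library, without the transcript pair, was lower in drought in leaf at 24 h and in root at 96 h, as most members were. In leaf at 96 h it moved differently from most members. In leaf it was 35.6% ± 2.37 in the 24 h controls and 18.8% ± 0.0122 in 24 h drought (mean ± SD, n = 2 each). At 96 h it was 28.4% ± 0.308 in controls and 33.8% ± 4.90 in drought, not lower although most members fell. In root at 96 h it was 0.907% ± 0.00984 in controls and 0.366% ± 0.0222 in drought.

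The 50 most abundant root-enriched transcripts moved differently as a sum and as members in root at 96 h. There 18 rose and 8 fell, while their summed share was 8.67% ± 0.0750 in controls and 5.91% ± 0.262 in drought (mean ± SD, n = 2 each).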
